A study of Homo sapiens with 8 samples.

How the data were processed

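RNA from human primary astrocytes was extracted with RNeasy columns and made into libraries with the TruSeq RNA v2 kit, per the labels. The 8 libraries fall into 4 groups of 2, labelled as biological replicates 1 and 2: vehicle (DMSO), IL1B at 20 ng/ml for 6 h, WIN at 10 µM for 24 h, and WIN for 24 h with IL1B for 6 h. The labels do not say what a replicate number shares between groups, nor how long WIN and IL1B overlapped. The deposited table holds raw counts per gene symbol and library, whole numbers without normalization. The authors' notes name bcl2fastq 2.20, STAR, HTSeq, DESeq2, DESeq and the build hg19, without giving the role of each tool. The annotation, the strand setting and any filter were not stated, so overlapping genes and near-identical copies are uncertain, and no coordinates are given. Of the 25382 symbols, 24252 were found in current gene name tables, and symbols were used as deposited, with older names accepted for the gene lists.

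Depth was 18847311 to 70558720 counts per library, and replicate 2 was the deeper library in every group. A single count corresponded to 0.0142 to 0.0531 CPM. The libraries of a group differed by more than counting error, with a chi-square per degree of freedom of 63.0 for vehicle, 21.9 for IL1B, 22.5 for WIN and 12.5 for WIN plus IL1B, so all 8 were kept as separate replicates. P-values of the gene tests rest on the spread between libraries of the same group, pooled over all 4 groups, with information on that spread shared across genes. Groups outside a contrast thus entered its p-values, and the spread was taken as equal although these chi-squares were not. With only the groups compared in the fit, IL1B lowered 735 genes instead of 1365. In WIN-treated cells it then raised 2726 instead of 1602.

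Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups as design, which left 15836. TMM factors ranged from 0.948 to 1.14. A quasi-likelihood model with robust dispersions (glmQLFit, glmQLFTest) was fitted to all 8 libraries with 1 mean per group and no other term, which left 4 residual degrees of freedom, and the biological coefficient of variation was 13.5%. Contrasts were IL1B against vehicle, WIN against vehicle, WIN plus IL1B against IL1B, WIN plus IL1B against WIN, the difference between both IL1B responses (interaction), and their average. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes, with no fold minimum. Standard errors were derived from the fold change and its F statistic. Levels are CPM with TMM factors, and log2 CPM used a prior count of 2. A rank or permutation test of 2 against 2 libraries cannot give a p below 0.333, so no such test was used.

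The 36 gene lists covered inflammatory, interferon, stress, lipid, growth and matrix pathways, markers of cell types that the cultures could hold, and RNA quality. Of these, 35 had at least 5 tested members and were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists of a contrast. Of the 21, 14, 24, 14 and 20 lists called for the contrasts in the order given up to the interaction, 10, 0, 0, 0 and 2 passed with a correlation estimated from the data. As a further alternative the lists were tested with fry in limma, which asks whether a list shifted up or down, whereas camera sets it against the other genes. The median of a list with a member at 0 counts in a group was also computed with that member at a bound of 3 counts. The genes named were, for the first 3 contrasts and the interaction, the 8 highest and 8 lowest log2 fold changes among called genes with a mean log2 CPM of at least 1 and, for pairs of groups, no overlap between libraries. To these came the 3 members with the smallest p of each called list, and a fixed set of inflammatory, astrocyte, cannabinoid and PPAR receptor genes. In WIN plus IL1B against WIN and in the average, where no such rule was set beyond the fixed genes, genes named for the other contrasts were followed, apart from COL3A1. Genes of the Y chromosome and of X inactivation were not named, and some genes that met the rule are not reported here. The grouping, contrasts, thresholds, lists, naming rule and most alternatives were chosen before the data were examined.

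Since WIN plus IL1B against IL1B and IL1B against vehicle share libraries, their covariance was set beside 100 simulated sets of unchanged counts, and their overlap was counted again with each comparison fitted from another IL1B library. The method was tested on simulated data with 200 changed genes among 15836. The test recovered 71% to 76% of 2-fold and 92% to 95% of 4-fold changes between groups, and 38% and 79% for the interaction, with 4.88% to 8.70% of calls false. In the data 16.1% to 67.2% of tested genes were called, far more than were changed in the simulation, so these rates may not carry over. With 1 list shifted, camera called 0 of 34 other lists. Simulated genes varied independently, so that check could not show false list calls that arise from correlated genes. Alternatives were a replicate block, DESeq2 1.42.0, limma-voom, other scaling factors, other low-count filters, a 2-fold minimum, an adjusted p under 0.01, the compared groups alone, and each library left out in turn, where the lone library of a group was assumed to vary like the others. Library totals without factors and libraries thinned to 18847311 counts were added after seeing the data. Replicate numbers were to be taken as pairs only if differences between replicates 1 and 2 correlated across genes above 0.1 for all 6 pairs of groups. The correlations were 0.36, 0.28, 0.19, 0.14, 0.054 and 0.29, so the block was kept as an alternative. Its fit called 5191 genes in IL1B against vehicle, 10297 in WIN against vehicle, 11727 in WIN plus IL1B against IL1B, 6798 in WIN plus IL1B against WIN and 4224 in the interaction. Permutations and figures used Python 3.11.15, with scipy 1.17.1, pandas 2.3.3 and numpy 2.4.6. For the uniform loss of the IL1B response, each gene was given the largest standard error of 3 contrasts, a choice made after a first version failed because errors near a fold change of 0 were unstable.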

Results

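RNA sequencing was used to measure gene expression in human primary astrocytes, the glial cells that surround and support neurons, under 4 conditions with 2 libraries each. Cells received the DMSO vehicle, interleukin 1 beta (IL1B, an inflammatory cytokine) at 20 ng/ml for 6 h, WIN (a synthetic agonist of cannabinoid receptors) at 10 µM for 24 h, or WIN for 24 h together with IL1B for 6 h. The labels do not say whether WIN was still present while IL1B was. Expression is given as CPM, counts scaled to a common effective library total, as mean ± SD of the 2 libraries of a group, and differences as log2 fold changes ± standard error. The count table named 25382 gene symbols, of which 4632 had no count and 15836 were tested. Total counts were 21384635 and 69789251 in the vehicle libraries (replicates 1 and 2), 20236288 and 63183052 with IL1B, 22792142 and 50390861 with WIN, and 18847311 and 70558720 with WIN plus IL1B. Between 17344 and 18990 symbols had a count in a library.

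The astrocyte marker GFAP, an intermediate filament protein, was expressed at 16666 ± 3035 CPM in vehicle cells, and the 21 tested astrocyte markers together summed to 24396 ± 3935 CPM. Markers of other cell types were measured in the same vehicle libraries. They summed to 4376 ± 1290.0 CPM for 15 fibroblast and mural cell genes, 1603 ± 128 CPM for 18 neuron genes, 797 ± 47.0 CPM for 12 oligodendrocyte lineage genes, 27.9 ± 4.90 CPM for 10 endothelial genes and 1.85 ± 0.527 CPM for 3 microglia and macrophage genes. On the first principal component, with 64.9% of the variance, the 4 libraries treated with WIN separated from the 4 without it. The second component, with 21.2%, separated the 4 libraries treated with IL1B from the other 4. Libraries of a group correlated across genes with a Pearson r of 0.988 for vehicle, 0.993 for IL1B, 0.992 for WIN and 0.994 for WIN plus IL1B (log2 CPM; genes are not independent replicates).

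**Figure D1:**
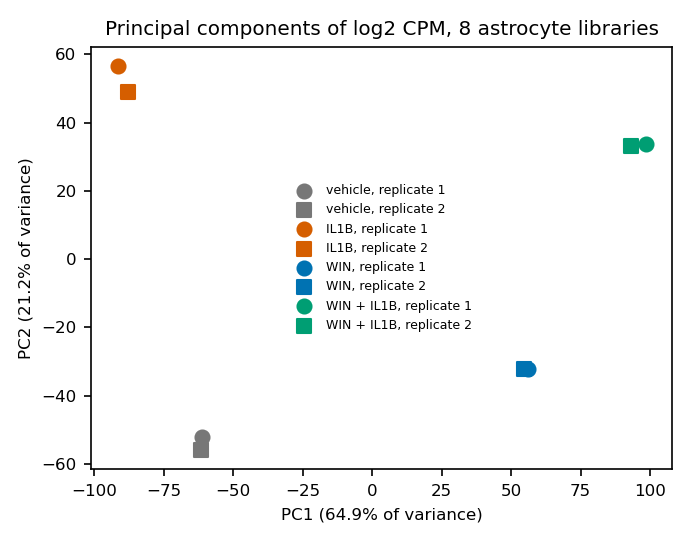
Principal components of log2 CPM of the 8 astrocyte libraries: the horizontal axis is PC1 (64.9% of the variance) and the vertical axis PC2 (21.2%), both in component scores. Colour marks the group and the marker shape the replicate number, and the 2 libraries of each group lie next to each other.

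The comparison of IL1B with vehicle addresses the response of astrocytes to an inflammatory cytokine. IL1B raised chemokines, cytokines, NF-kB feedback genes and interferon-stimulated genes many fold. The neutrophil chemoattractant CXCL8 rose from 2.40 ± 0.610 to 2039.6 ± 218 CPM, a log2 fold change of 9.68 ± 0.38 (adjusted p = 2.7e-09, edgeR's quasi-likelihood test). The antiviral GTPase MX1 rose from 5.08 ± 0.631 to 1218 ± 122 CPM, by 7.89 ± 0.22 (adjusted p = 4.3e-10, edgeR). GFAP was lower with IL1B, at 5983 ± 996 CPM, a log2 fold change of -1.48 ± 0.17 (adjusted p = 5.5e-05, edgeR). In total 1821 genes were higher and 1365 lower at a Benjamini-Hochberg adjusted p under 0.05 in edgeR, and 1033 and 491 of them changed at least 2-fold.

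The 8 genes with the highest log2 fold changes were CXCL3, CCL20, CXCL2, CXCL10, CXCL1, CXCL8, TNFAIP2 and RSAD2, between 10.16 ± 0.36 for CXCL3 and 9.04 ± 0.35 for RSAD2. Of 19 tested chemokines, 17 rose and none fell, 18 when adjusted over the list alone, with a median log2 fold change of 8.48 (camera adjusted p = 7.2e-23, and adjusted p = 0.048 with an estimated correlation). All 19 tested genes of the NF-kB list rose, also when adjusted over the list alone, with a median of 4.08 (camera adjusted p = 1.2e-25, and adjusted p = 0.044 with an estimated correlation). They included the feedback inhibitors TNFAIP3 at 7.03 ± 0.19 and NFKBIA at 4.03 ± 0.17 and the apoptosis inhibitor BIRC3 at 7.99 ± 0.24. Of 25 cytokines and growth factors, 24 rose and none fell, the same numbers as when adjusted over the list alone (camera adjusted p = 1.2e-25, and adjusted p = 0.029 with an estimated correlation). Among these, the neurotrophic cytokine LIF rose by 5.63 ± 0.18 to 1316 ± 65.1 CPM, IL11 by 4.76 ± 0.18 and IL6 by 7.84 ± 0.43. CSF2, a growth factor for myeloid cells, went from 0.0135 ± 0.0192 to 63.3 ± 3.95 CPM.

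Of 17 adhesion and matrix protease genes, 13 rose and none fell, 14 when adjusted over the list alone (camera adjusted p = 8.1e-15, and adjusted p = 0.047 with an estimated correlation). The leukocyte adhesion receptors ICAM1 and VCAM1 rose by 7.92 ± 0.27 and 5.24 ± 0.20, and the metalloproteinases ADAMTS9 and MMP7 by 5.60 ± 0.16 and 4.37 ± 0.15. Enzymes of prostaglandin, nitric oxide and superoxide metabolism rose in 10 of 16 cases and fell in 1, with the same counts when adjusted over the list alone (camera adjusted p = 2.4e-07, and adjusted p = 0.044 with an estimated correlation). NOS2, the inducible nitric oxide synthase, rose by 7.82 ± 0.25, PTGS2, the inducible cyclooxygenase, by 8.87 ± 0.30, and mitochondrial superoxide dismutase SOD2 by 5.07 ± 0.15. Type I interferon-stimulated genes rose in 37 of 38 cases, and in 38 when adjusted over the list alone, with a median of 4.66 (camera adjusted p = 1e-44, and adjusted p = 0.039 with an estimated correlation). IFIT1 rose by 6.50 ± 0.20, and CMPK2 by 6.88 ± 0.19. Of 29 genes of antigen presentation and the interferon gamma response, 24 rose and 1 fell, the same when adjusted over the list alone (camera adjusted p = 4.7e-18, and adjusted p = 0.10 with an estimated correlation), among them the transcription factor IRF1 at 4.53 ± 0.18.

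Of 29 reactive astrocyte genes, 19 rose and 1, GFAP, fell, and 20 rose when adjusted over the list alone (camera adjusted p = 3.1e-13, and adjusted p = 0.034 with an estimated correlation). Among 17 complement and acute phase genes, 9 rose and none fell, as when adjusted over the list alone (camera adjusted p = 7e-07, and adjusted p = 0.047 with an estimated correlation). Pentraxin PTX3 rose by 6.95 ± 0.21, complement C3 by 6.43 ± 0.28 and the protease inhibitor SERPINA3 by 3.83 ± 0.20. The receptor for IL1B, IL1R1, rose by 1.77 ± 0.17 (adjusted p = 7.3e-06, edgeR). Of 21 astrocyte markers 8 fell and none rose, 9 when adjusted over the list alone, with a median of -0.31 (camera adjusted p = 0.00017, and adjusted p = 0.047 with an estimated correlation). They included the potassium channel KCNJ10 at -2.33 ± 0.15. The 8 genes with the lowest log2 fold changes were PIRT, FOXJ1, NXPH3, USP2, DEPTOR, RASGEF1A, EDNRB and LRRC3B. They ranged from -3.64 ± 0.21 for PIRT, a regulator of sensory ion channels, to -2.41 ± 0.20 for LRRC3B. FOXJ1, a master regulator of motile cilia, fell by 3.40 ± 0.27. The endothelin receptor gene EDNRB went from 90.4 ± 4.89 to 16.2 ± 1.44 CPM.

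None of 36 cell cycle genes passed the test in either direction in edgeR (median -0.06, camera adjusted p = 0.38). The cannabinoid receptor gene CNR1 had a log2 fold change of -0.64 ± 0.17 with IL1B (adjusted p = 0.018, edgeR), which did not pass without vehicle replicate 1 (adjusted p = 0.079), without IL1B replicate 2 (adjusted p = 0.17) or with only the groups compared in the fit (adjusted p = 0.081). The nuclear receptor genes PPARA, at -0.35 ± 0.17 (adjusted p = 0.19, edgeR), and PPARG, at 1.07 ± 0.44 (adjusted p = 0.11, edgeR), did not pass. In edgeR PPARA passed with library totals (adjusted p = 0.038), and PPARG with a replicate block (adjusted p = 0.017) or no low-count filter (adjusted p = 0.026). The share of called genes that were higher was 57.2%, against 37.8% with upper-quartile factors (1499 higher, 2471 lower) and 31.1% with library totals (1390 higher, 3084 lower), scalings that shifted the median gene by -0.14 and -0.20. Without IL1B replicate 1 or 2, 513 and 631 genes were lower.

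The comparison of WIN with vehicle addresses the effect of a cannabinoid receptor agonist on unstimulated astrocytes. WIN raised genes of the endoplasmic reticulum stress and integrated stress responses and lowered cell cycle genes and markers of the astrocyte, progenitor and oligodendrocyte lineages. None of the 14 lists that passed limma's camera here, these included, passed with an estimated correlation. HSPA5, the main chaperone of the endoplasmic reticulum, rose from 581 ± 58.8 to 9508 ± 236 CPM, a log2 fold change of 4.03 ± 0.16 (adjusted p = 2.6e-08, edgeR). DDIT3, a transcription factor of the stress response, rose from 14.5 ± 1.15 to 198 ± 17.7 CPM, by 3.77 ± 0.16 (adjusted p = 2.6e-08, edgeR). The mitotic topoisomerase TOP2A went from 149 ± 30.3 to 20.3 ± 0.608 CPM, a change of -2.88 ± 0.17 (adjusted p = 2.3e-07, edgeR). In total 4346 genes were higher and 4413 lower in edgeR, 55.3% of those tested, and 2253 and 2150 changed at least 2-fold.

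All 17 tested endoplasmic reticulum stress genes rose, also when adjusted over the list alone, with a median of 2.24 (camera adjusted p = 9.1e-10, but adjusted p = 0.11 with an estimated correlation). HERPUD1, a factor of protein degradation, rose by 3.73 ± 0.15 and the chaperone HSP90B1 by 2.79 ± 0.14. Of 24 integrated stress response genes, 22 rose and none fell, 23 when adjusted over the list alone, with a median of 1.95 (camera adjusted p = 4.3e-11, but adjusted p = 0.11 with an estimated correlation). CHAC1, which degrades glutathione, rose by 3.98 ± 0.19 and asparagine synthetase ASNS by 2.73 ± 0.15. The 8 genes with the highest log2 fold changes were DUSP9, CLDN3, C17orf107, CYP27B1, KCNK6, INHBE, ICAM5 and DERL3. DUSP9, a phosphatase acting on MAP kinases, rose by 7.09 ± 0.30 and CLDN3, a tight junction protein, by 6.75 ± 0.25, from 0.639 ± 0.0920 to 71.6 ± 5.28 CPM. DERL3, a component of protein export from the endoplasmic reticulum, rose by 5.10 ± 0.21. C17orf107 is a gene of unassigned function, and since strand use was not stated its counts could include transcripts of overlapping genes.

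Of 36 cell cycle genes, 31 fell and 1 rose, the same when adjusted over the list alone, with a median of -1.75 (camera adjusted p = 6.2e-10, but adjusted p = 0.11 with an estimated correlation). Besides TOP2A, these included NUSAP1, a protein of the mitotic spindle, at -2.72 ± 0.17 and the ribonucleotide reductase subunit RRM2 at -2.44 ± 0.16. Of 21 astrocyte markers, 17 fell and 1 rose, the same when adjusted over the list alone, with a median of -1.24 (camera adjusted p = 1.1e-05, but adjusted p = 0.11 with an estimated correlation). Among those that fell were GFAP at -1.64 ± 0.17, the water channel AQP4 at -2.35 ± 0.17, glutamine synthetase GLUL at -1.96 ± 0.13 and KCNJ10 at -1.98 ± 0.15. Oligodendrocyte lineage markers fell in 11 of 12 cases, also when adjusted over the list alone, where 1 rose (camera adjusted p = 3.6e-05, but adjusted p = 0.11 with an estimated correlation). SOX10, a transcription factor of that lineage, went from 9.86 ± 4.02 to 0.479 ± 0.177 CPM, by -4.28 ± 0.34, and the growth factor receptor PDGFRA fell by 2.24 ± 0.13. Neural progenitor markers fell in 10 of 12 cases, in 11 when adjusted over the list alone (camera adjusted p = 0.0017, but adjusted p = 0.11 with an estimated correlation), with the receptor NOTCH1 at -1.88 ± 0.22. The genes with the lowest log2 fold changes included SOX10, C11orf87, SMOC1, DIO3, GSX2, OLIG1 and APOL4, the last at -3.50 ± 0.23.

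Cholesterol synthesis genes rose in 14 of 26 cases and fell in 2, or 15 and 3 when adjusted over the list alone (camera adjusted p = 0.013, but adjusted p = 0.22 with an estimated correlation). The enzymes SQLE and DHCR7 rose by 1.25 ± 0.13 and 1.10 ± 0.14. In unstimulated cells 24 of 38 type I interferon-stimulated genes fell with WIN and 7 rose, the same when adjusted over the list alone, with a median of -0.70 (camera adjusted p = 0.0088, but adjusted p = 0.55 with an estimated correlation). That list did not pass the camera test once WIN replicate 1 was left out (limma's camera, adjusted p = 0.056). IFITM1, at -2.29 ± 0.19, and MX1, at -0.63 ± 0.19, were among those that fell. Of 29 genes of antigen presentation, 18 fell and 2 rose, the same when adjusted over the list alone (camera adjusted p = 0.0047, but adjusted p = 0.55 with an estimated correlation). The class II gene HLA-DRA, at -1.83 ± 0.13, and its transactivator CIITA, at -1.96 ± 0.17, were lower, and how reads shared among related HLA genes were counted was not stated.

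Inflammatory mediators were mixed in unstimulated cells. ICAM1 rose by 0.92 ± 0.21 (adjusted p = 0.0028, edgeR), while VCAM1 (-1.79 ± 0.18), SOD2 (-1.15 ± 0.13), SERPINA3 (-0.90 ± 0.18), NFKBIA (-0.66 ± 0.16) and IL1R1 (-0.94 ± 0.17) fell. CCL2 at -0.21 ± 0.18, CXCL10 at 0.03 ± 0.31, TNFAIP3 at 0.17 ± 0.17, C3 at -0.86 ± 0.42 and PPARG at 0.79 ± 0.45 did not pass, and PPARG did without WIN replicate 1 (adjusted p = 0.032, edgeR). IL6 had 0.101 ± 0.142 CPM with WIN and 0.224 ± 0.0851 CPM with vehicle, with 0 counts in WIN replicate 1, and did not pass (adjusted p = 0.35, edgeR). CXCL8, at -0.20 ± 0.34, passed once WIN replicate 2 was left out (adjusted p = 0.013, edgeR), as did IL6 (adjusted p = 0.050, edgeR). CNR1 fell by 1.49 ± 0.17, and PPARA rose by 0.89 ± 0.17. CNR2, the second cannabinoid receptor gene, had between 0 and 2 counts per library and was not tested. Mitochondrial transcripts took 1.12% to 1.24% of counts in vehicle libraries and 1.36% to 1.66% with WIN. Their list rose in 6 of 13 cases, the same when adjusted over the list alone (camera adjusted p = 0.047, but adjusted p = 0.55 with an estimated correlation), and the call was lost without vehicle replicate 2 (0.10), IL1B replicate 1 (0.051), IL1B replicate 2 (0.056) or WIN replicate 1 (0.19), and with the stricter low-count filter (0.051). The share of called genes that were higher with WIN was 49.6%, against 41.3% with upper-quartile factors (3713 higher, 5286 lower) and 39.7% with library totals (3587 higher, 5445 lower), which shifted the median gene by -0.13 and -0.15.

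**Figure D2:**
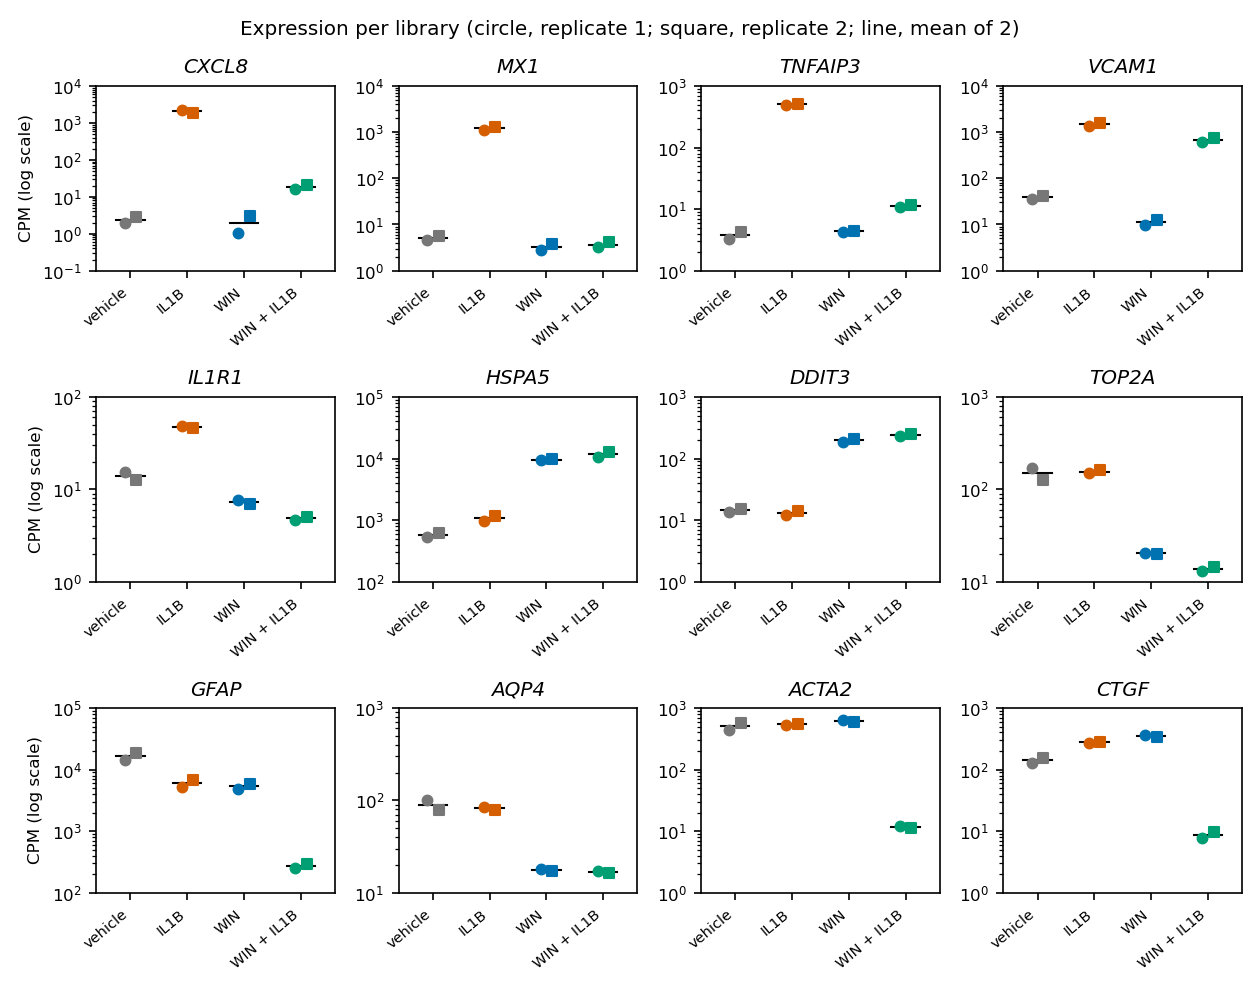
Expression of 12 genes named in the text, in CPM on a log axis per library, with the group on the horizontal axis (circle, replicate 1; square, replicate 2; line, mean of 2). CXCL8, MX1 and TNFAIP3 are high with IL1B alone, HSPA5 and DDIT3 are high in both WIN groups, and ACTA2 and CTGF are low in WIN plus IL1B, at 11.7 and 8.66 CPM.

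The comparison of WIN plus IL1B with IL1B addresses how WIN changed stimulated astrocytes. Most of the inflammatory transcripts raised by IL1B were lower with WIN, although none of the 24 lists that passed limma's camera passed with an estimated correlation. The 38 tested interferon-stimulated genes, which summed to 999.9 ± 28.2 CPM with vehicle and 14903 ± 785 CPM with IL1B, summed to 796 ± 12.5 CPM with WIN plus IL1B. MX1 was at 3.65 ± 0.617 CPM with WIN plus IL1B against 1218 ± 122 CPM with IL1B, a log2 fold change of -8.35 ± 0.23 (adjusted p = 5.1e-10, edgeR), and at 5.08 ± 0.631 CPM in vehicle cells. CXCL8 was at 18.5 ± 2.53 CPM, which was -6.78 ± 0.33 from IL1B alone (adjusted p = 1e-08, edgeR). ICAM1 and VCAM1 kept 629.8 ± 26.8 and 673 ± 105 CPM, with smaller decreases, -1.68 ± 0.20 (adjusted p = 1.3e-05, edgeR) and -1.13 ± 0.17 (adjusted p = 8.3e-05, edgeR). In total 4911 genes were higher and 5730 lower in edgeR, 67.2% of those tested, and 2766 and 3960 changed at least 2-fold.

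Of the 1821 genes raised by IL1B, 1321 (72.5%) were lower with WIN in stimulated cells and 235 were higher. Lists drawn independently would share 659 and 565. Genes of the Y chromosome and of X inactivation aside, the interaction was called negative for 949 of the 1321 and positive for 1. For the others a smaller response to IL1B was not shown. Of the 1365 genes lowered by IL1B, 439 were higher and 524 lower with WIN, against 423 and 494 for independent lists. Those 439 and 524 were 133 and 206 without IL1B replicate 1, 196 and 208 without IL1B replicate 2, 276 and 376 without WIN plus IL1B replicate 1 and 278 and 346 without WIN plus IL1B replicate 2, and 622 and 576 with no low-count filter. The 235 raised in both were 92 and 102 without IL1B replicate 1 and 2, 142 and 133 without WIN plus IL1B replicate 1 and 2, and 601 without vehicle replicate 1. Both comparisons use the IL1B libraries with opposite sign, so part of any opposition arises from shared error. In 100 simulated sets of unchanged counts that error alone gave the log2 fold changes a median r of -0.505 and a median covariance of -0.0367 across genes, where r of -0.381 and a covariance of -0.615 were observed. With the response to IL1B taken from IL1B replicate 1 and the effect of WIN from IL1B replicate 2, so that no library was shared, 983 of 1354 raised genes (72.6%) were lower with WIN in edgeR, against 443 for independent lists. With the 2 IL1B libraries exchanged it was 984 of 1281 (76.8%), against 401.

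Type I interferon-stimulated genes fell in 37 of 38 cases and rose in 1, the same when adjusted over the list alone, with a median of -4.37 (camera adjusted p = 2.5e-15, but adjusted p = 0.12 with an estimated correlation). The lowest were RSAD2, an antiviral enzyme, at -9.05 ± 0.36, IFIT1 at -8.49 ± 0.22, MX1, OAS1 at -7.90 ± 0.30 and IFIT3 at -7.55 ± 0.23. All 19 chemokines fell, also when adjusted over the list alone, with a median of -5.57, or -5.45 with a member at 0 counts placed at its bound (camera adjusted p = 1.7e-08, but adjusted p = 0.15 with an estimated correlation). CXCL2 changed by -6.64 ± 0.20, CXCL10 by -6.11 ± 0.26 and CCL2, which attracts monocytes, by -4.15 ± 0.20. CXCL14 did not pass with IL1B alone (81.5 ± 5.10 CPM, vehicle 80.2 ± 9.02 CPM) and was at 2.81 ± 0.0301 CPM with WIN plus IL1B. Of 25 cytokines and growth factors 24 fell and 1 rose, the same when adjusted over the list alone (camera adjusted p = 5.7e-08, but adjusted p = 0.12 with an estimated correlation). LIF changed by -6.79 ± 0.19, IL11 by -5.48 ± 0.19 and the macrophage growth factor CSF1 by -6.26 ± 0.25. IL6 fell by 8.48 ± 0.47 to 0.104 ± 0.147 CPM, with 0 and 14 counts in the WIN plus IL1B libraries.

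NF-kB genes fell in 17 of 19 cases and rose in 2, the same when adjusted over the list alone, with a median of -2.67 (camera adjusted p = 2.4e-06, but adjusted p = 0.16 with an estimated correlation). TNFAIP3 changed by -5.46 ± 0.18, BIRC3 by -6.24 ± 0.22 and NFKBIA by -3.61 ± 0.17. Adhesion and matrix protease genes fell in all 17 cases, also when adjusted over the list alone (camera adjusted p = 3.3e-07, but adjusted p = 0.12 with an estimated correlation), with the plasminogen activator PLAU at -5.27 ± 0.19. Of 29 reactive astrocyte genes 27 fell and 1 rose, the same when adjusted over the list alone (camera adjusted p = 4e-09, but adjusted p = 0.12 with an estimated correlation). GFAP fell by 4.46 ± 0.20 to 272 ± 24.7 CPM. NOS2 (-7.75 ± 0.25), SOD2 (-3.12 ± 0.14), C3 (-3.05 ± 0.22) and SERPINA3 (-2.35 ± 0.19) also fell. IL1R1 fell by 3.29 ± 0.18 to 4.84 ± 0.232 CPM, and SOCS3, an inhibitor of cytokine signalling, fell by 4.73 ± 0.19. IRAK3, an inhibitor of toll-like and interleukin 1 receptor signalling, rose by 4.56 ± 0.24, from 1.16 ± 0.0534 to 27.8 ± 0.283 CPM. The remaining genes among the 8 lowest were TGM2, a transglutaminase, at -7.76 ± 0.26, and PI15, at -7.51 ± 0.35.

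Endoplasmic reticulum stress genes rose in 16 of 17 cases, also when adjusted over the list alone (median 2.04, camera adjusted p = 8.2e-08, but adjusted p = 0.12 with an estimated correlation). Integrated stress response genes rose in 22 of 24 cases and fell in 2, the same when adjusted over the list alone (median 2.65, camera adjusted p = 7.5e-09, but adjusted p = 0.12 with an estimated correlation). HSPA5 reached 11673 ± 1256 CPM, DDIT3 rose by 4.21 ± 0.16 and ASNS by 3.50 ± 0.15. The 8 genes with the highest log2 fold changes were INHBE, KCNK6, CYP27B1, DUSP9, C17orf107, CLDN3, MPV17L and CHAC1, from 7.56 ± 0.30 for INHBE, a subunit of activin E, to 5.64 ± 0.20 for CHAC1. The effects of WIN with and without IL1B shared 3643 genes raised and 3747 lowered, against 1348 and 1597 for independent lists, while 167 and 27 genes went opposite ways, together 194, or 309 without vehicle replicate 2 and 126 without WIN replicate 2. These comparisons share no library, and their log2 fold changes correlated across genes with r of 0.738.

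Cell cycle genes fell in 28 of 36 cases and rose in 4, the same when adjusted over the list alone (median -2.37, camera adjusted p = 1.5e-06, but adjusted p = 0.12 with an estimated correlation), with RRM2 at -4.67 ± 0.19. Of 28 TGF-beta and extracellular matrix genes 24 fell and 2 rose, the same when adjusted over the list alone (median -1.87, camera adjusted p = 5e-06, but adjusted p = 0.22 with an estimated correlation). CTGF, a matricellular growth factor, changed by -4.98 ± 0.18 and thrombospondin THBS1 by -4.89 ± 0.19. Fibroblast and mural markers fell in 11 of 15 cases and rose in 1, or 12 and 1 when adjusted over the list alone (camera adjusted p = 0.0016, but adjusted p = 0.21 with an estimated correlation). Smooth muscle actin ACTA2 fell by 5.55 ± 0.18, from 544 ± 8.98 to 11.7 ± 0.343 CPM. Astrocyte markers fell in 16 of 21 cases, also when adjusted over the list alone (camera adjusted p = 0.00045, but adjusted p = 0.12 with an estimated correlation), among them GLUL at -3.02 ± 0.14 and the folate enzyme ALDH1L1 at -3.30 ± 0.23. Oligodendrocyte lineage markers fell in 11 of 12 (camera adjusted p = 5.5e-05, but adjusted p = 0.12 with an estimated correlation), and endothelial markers in 8 of 10 (camera adjusted p = 0.011, but adjusted p = 0.23 with an estimated correlation), with the same counts when adjusted over each list alone. CNR1 fell by 1.76 ± 0.18 and PPARA rose by 2.08 ± 0.18. PPARG had a log2 fold change of -1.70 ± 0.48 (adjusted p = 0.0079, edgeR), which did not pass without IL1B replicate 2 (adjusted p = 0.18), without WIN plus IL1B replicate 2 (adjusted p = 0.082) or with libraries thinned to equal depth (adjusted p = 0.14).

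**Figure D3:**
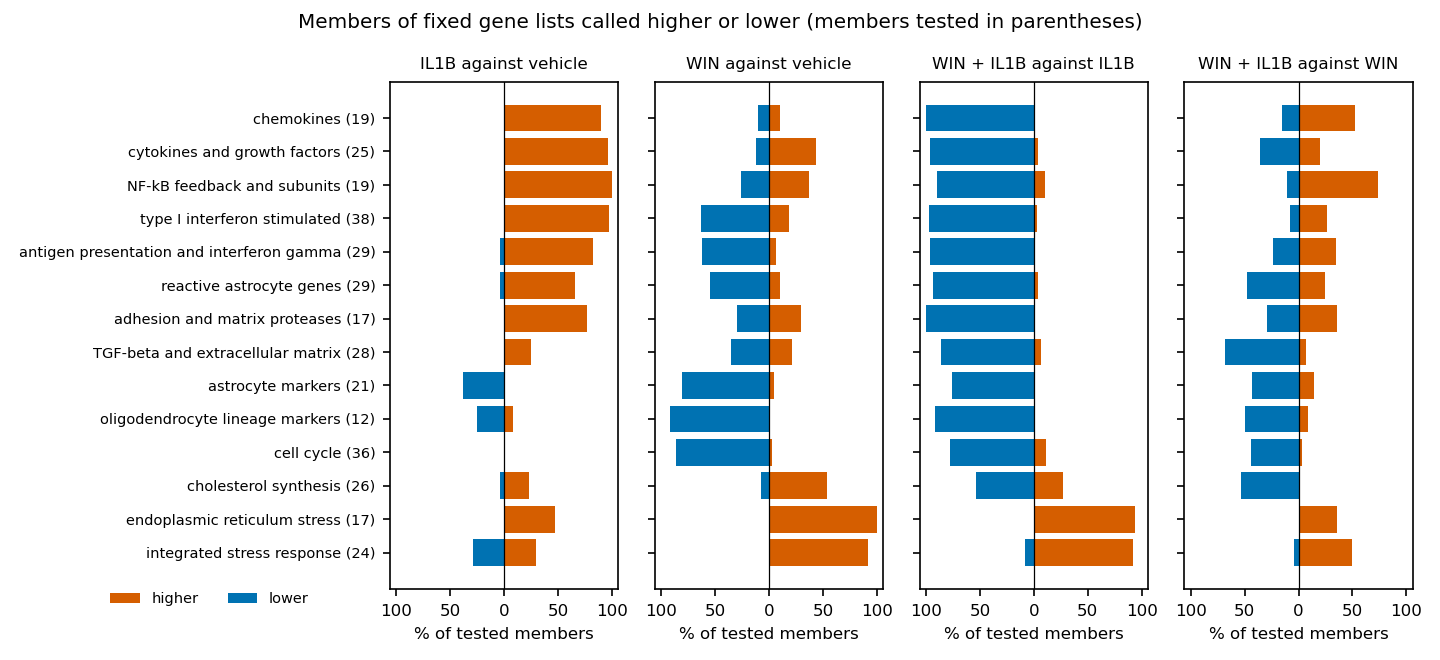
Members of 14 fixed gene lists called higher (orange, right) or lower (blue, left) in 4 comparisons, as a percentage of the tested members on the horizontal axis, with the number tested in parentheses. In WIN plus IL1B against IL1B all 19 chemokines were lower and 16 of 17 endoplasmic reticulum stress genes were higher.

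The comparison of WIN plus IL1B with WIN addresses what IL1B did in cells treated with WIN. Some inflammatory genes still rose, while most genes of the TGF-beta and matrix list and of the histone list fell. None of the 14 lists that passed limma's camera in this comparison passed with an estimated correlation. VCAM1 rose from 11.2 ± 2.04 to 673 ± 105 CPM, by 5.89 ± 0.21 (adjusted p = 8.8e-09, edgeR), and ICAM1 by 5.32 ± 0.24 (adjusted p = 4.3e-08, edgeR). CCL20, a lymphocyte chemoattractant, rose by 6.07 ± 0.30 and TNFAIP2 by 5.59 ± 0.26. ACTA2 went from 621 ± 36.7 to 11.7 ± 0.343 CPM, a change of -5.74 ± 0.18 (adjusted p = 8.8e-09, edgeR). In total 1602 genes were higher and 2773 lower in edgeR, 27.6% of those tested, and 273 and 1626 changed at least 2-fold.

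NF-kB genes rose in 14 of 19 cases and fell in 2, or 15 and 2 when adjusted over the list alone, with a median of 0.98 (camera adjusted p = 4.6e-07, but adjusted p = 0.29 with an estimated correlation). NFKBIA rose by 1.08 ± 0.16 and TNFAIP3 by 1.40 ± 0.17. Chemokines rose in 10 of 19 cases and fell in 3, the same when adjusted over the list alone (camera adjusted p = 0.0015, but adjusted p = 0.45 with an estimated correlation). CXCL8 rose by 3.10 ± 0.32, while CCL2 (-1.33 ± 0.18) and CXCL14 (-5.37 ± 0.18) fell. SOD2 rose by 3.11 ± 0.14 and SERPINA3 by 2.38 ± 0.19. Cytokines and growth factors were split, with 5 of 25 higher and 9 lower in edgeR, or 7 and 10 when adjusted over the list alone, and limma's camera gave an adjusted p = 0.91. LIF fell by 1.39 ± 0.16. Of 38 type I interferon-stimulated genes 10 rose and 3 fell, the same when adjusted over the list alone, with a median of 0.11 (camera adjusted p = 0.043, but adjusted p = 0.59 with an estimated correlation). That call was lost without vehicle replicate 1 (0.058), vehicle replicate 2 (0.062), WIN replicate 1 (0.29) or WIN plus IL1B replicate 2 (0.091), and with a replicate block (0.059), the stricter low-count filter (0.051) or fry (0.097). MX1 at 0.17 ± 0.20, RSAD2 at 0.33 ± 0.42 and IFIT1 at -0.24 ± 0.20 did not pass.

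TGF-beta and extracellular matrix genes fell in 19 of 28 cases and rose in 2, or 20 and 2 when adjusted over the list alone (camera adjusted p = 4.6e-07, but adjusted p = 0.32 with an estimated correlation). CTGF changed by -5.33 ± 0.18 and THBS1 by -4.66 ± 0.18. Fibroblast and mural markers fell in 10 of 15 cases and rose in 2, the same when adjusted over the list alone (camera adjusted p = 0.0020, but adjusted p = 0.32 with an estimated correlation). Their summed level was 6590.3 ± 529 CPM with WIN and 2212 ± 319 CPM with WIN plus IL1B. The actin-binding protein gene TAGLN fell by 4.25 ± 0.23, and collagen COL3A1, chosen after its value was seen, rose by 1.19 ± 0.20. On several other cell type lists more markers fell than rose. Astrocyte markers fell in 9 of 21 cases and rose in 3 (median -0.28, camera adjusted p = 0.043, but adjusted p = 0.29 with an estimated correlation), the same when adjusted over the list alone, and summed to 8699 ± 1022 CPM with WIN and 3313 ± 228 CPM with both. Most of that fall in the sum was GFAP, at 5359.9 ± 736 CPM with WIN and 254.7 and 289.6 CPM in the libraries with both. Neural progenitor markers fell in 5 of 12 cases, or 6 when adjusted over the list alone (median -0.47, camera adjusted p = 0.043, but adjusted p = 0.29 with an estimated correlation). Oligodendrocyte lineage markers fell in 6 of 12 and rose in 1, or 7 and 1 when adjusted over the list alone (median -0.81, camera adjusted p = 0.043, but adjusted p = 0.29 with an estimated correlation). These 3 calls were lost without vehicle replicate 1 (0.051, 0.051 and 0.054), WIN replicate 1 (0.065 each) or WIN plus IL1B replicate 2 (0.080, 0.084 and 0.056). The astrocyte call was also lost without vehicle replicate 2 (0.051), and the oligodendrocyte call without vehicle replicate 2 (0.057) or IL1B replicate 1 (0.051), with a replicate block (0.085) and with the stricter low-count filter (0.080). Endothelial markers fell in 4 of 10 cases and rose in 1, the same when adjusted over the list alone (median -1.12), and did not pass (camera adjusted p = 0.13), but did without WIN replicate 2 (0.043), with the stricter low-count filter (0.031) or with fry (0.0028). Replication-dependent histone genes fell in 7 of 8 cases, also when adjusted over the list alone (median -1.66, camera adjusted p = 0.00013, but adjusted p = 0.29 with an estimated correlation). Cholesterol synthesis genes fell in 14 of 26 cases and none rose, the same when adjusted over the list alone (median -0.57, camera adjusted p = 0.00044, but adjusted p = 0.29 with an estimated correlation). Cell cycle genes fell in 16 of 36 cases and rose in 1, or 17 and 2 when adjusted over the list alone (camera adjusted p = 0.0056, but adjusted p = 0.32 with an estimated correlation). Integrated stress response genes rose in 12 of 24 cases and fell in 1, or 15 and 1 when adjusted over the list alone (camera adjusted p = 3e-05, but adjusted p = 0.29 with an estimated correlation). GFAP fell by 4.30 ± 0.19, from 5359.9 ± 736 CPM, and TGM2 fell by 4.18 ± 0.24. The share of called genes that were higher was 36.6%, against 43.7% with RLE factors (1998 higher, 2570 lower), 26.7% with upper-quartile factors (1158 higher, 3184 lower) and 29.4% with library totals (1258 higher, 3020 lower). The number of genes higher was 2764 without vehicle replicate 1, 2652 without vehicle replicate 2, 907 without WIN replicate 1, 354 without WIN replicate 2, 572 without WIN plus IL1B replicate 1 and 382 without WIN plus IL1B replicate 2. The number lower was 1545 without WIN replicate 2, 1634 without WIN plus IL1B replicate 1 and 1333 without WIN plus IL1B replicate 2.

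The difference between both responses to IL1B, with and without WIN, was tested as an interaction. The response of most inflammatory, interferon and matrix genes on the fixed lists was lower in WIN-treated cells. Of the 20 lists that passed limma's camera, 2 passed with an estimated correlation, cytokines and growth factors and reactive astrocyte genes. TGM2 differed by -9.05 ± 0.32 (adjusted p = 1.1e-08, edgeR), as it rose from 7.21 ± 1.61 to 214 ± 7.09 CPM without WIN and fell from 17.9 ± 0.445 to 0.892 ± 0.339 CPM with it. MX1 differed by -7.72 ± 0.28 (adjusted p = 1.1e-08, edgeR) and CXCL8 by -6.58 ± 0.45 (adjusted p = 9.1e-07, edgeR). In total the interaction was positive for 509 genes and negative for 2044 in edgeR, at least 2-fold for 239 and 1683.

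The 8 lowest interactions were TGM2, RSAD2, OAS1, MX1, LIF, KRT75, BIRC3 and IFIT1, the last at -6.74 ± 0.26. Type I interferon-stimulated genes had a negative interaction in 37 of 38 cases, and in 38 when adjusted over the list alone, with a median of -4.35 (camera adjusted p = 2.3e-36, but adjusted p = 0.052 with an estimated correlation). For cytokines and growth factors it was 22 of 25, or 23 when adjusted over the list alone, with a median of -4.73, or -4.86 with members at 0 counts placed at their bound (camera adjusted p = 1.2e-20, and adjusted p = 0.023 with an estimated correlation). For chemokines it was 15 of 19, or 17 when adjusted over the list alone (camera adjusted p = 2.9e-18, but adjusted p = 0.067 with an estimated correlation). For NF-kB genes it was 16 of 19, or 17 when adjusted over the list alone, with a median of -2.95 (camera adjusted p = 2.5e-17, but adjusted p = 0.060 with an estimated correlation). Reactive astrocyte genes had a negative interaction in 24 of 29 cases, or 25 when adjusted over the list alone (camera adjusted p = 2.5e-17, and adjusted p = 0.023 with an estimated correlation). TNFAIP3 differed by -5.63 ± 0.24, CCL2 by -3.94 ± 0.26, NFKBIA by -2.95 ± 0.22, ICAM1 by -2.60 ± 0.29, SOD2 by -1.96 ± 0.18 and IL1R1 by -2.34 ± 0.24. VCAM1 differed by 0.66 ± 0.24 and did not pass (adjusted p = 0.094, edgeR). It passed in edgeR with a replicate block (adjusted p = 0.0032), upper-quartile factors (adjusted p = 0.049), library totals (adjusted p = 0.028) or no low-count filter (adjusted p = 0.0086), and without vehicle replicate 1 (adjusted p = 0.048).

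TGF-beta and matrix genes had a negative interaction in 21 of 28 cases and a positive one in 2, or 22 and 3 when adjusted over the list alone (camera adjusted p = 3.6e-10, but adjusted p = 0.16 with an estimated correlation). CTGF differed by -6.30 ± 0.23 and ACTA2 by -5.85 ± 0.23. Cholesterol synthesis genes had a negative interaction in 13 of 26 cases, or 18 when adjusted over the list alone (camera adjusted p = 6.4e-06, but adjusted p = 0.060 with an estimated correlation). Their member INSIG1 differed by -1.74 ± 0.23. Integrated stress response genes had a positive interaction in 7 of 24 cases and a negative one in 2, or 12 and 3 when adjusted over the list alone (camera adjusted p = 0.0016, but adjusted p = 0.27 with an estimated correlation and 0.074 with limma's fry). Among them CHAC1 differed by 1.67 ± 0.25 and the tryptophan tRNA synthetase WARS, which rose with IL1B alone from 156 ± 13.3 to 1224 ± 39.3 CPM, by -2.60 ± 0.18. The 8 highest interactions were PIRT, USP2, KLF15, SLCO1C1, WDR96, SMOC1, CPEB1 and PPP1R3C, from 3.52 ± 0.27 for PIRT to 2.05 ± 0.28 for PPP1R3C. PIRT was at 17.4 ± 2.44 CPM with vehicle, 1.39 ± 0.0140 CPM with IL1B, 18.8 ± 1.95 CPM with WIN and 17.3 ± 0.532 CPM with both. GFAP differed by -2.82 ± 0.25 and PPARA by 1.19 ± 0.24, while CNR1, at -0.27 ± 0.24, did not pass (adjusted p = 0.51, edgeR). The share of called interactions that were positive was 19.9%, against 36.6% with library totals (980 positive, 1695 negative), which shifted the median gene by 0.16. Positive calls numbered 1231 without vehicle replicate 2, 229 and 222 without IL1B replicate 1 and 2, 290 and 148 without WIN replicate 1 and 2, and 180 without either WIN plus IL1B replicate, and negative calls 1360 without WIN plus IL1B replicate 2.

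Genes called in the average of both responses to IL1B, a contrast orthogonal to the interaction, numbered 2494 raised and 3212 lowered in edgeR. Of the 2494 raised genes, among them CXCL8, ICAM1 and SOD2, 687 responded less and 85 more in WIN-treated cells, and the median log2 response was 0.60 without WIN and 0.49 with it. Of the 3212 lowered genes, among them GFAP and KCNJ10, 117 responded less and 825 more, with medians of -0.52 and -0.94. Both responses had the direction of the average in 447 of the 687 and 41 of the 85 raised genes, and in 66 of the 117 and 524 of the 825 lowered ones, while in the others the smaller of both responses did not. KCNJ10 differed by 0.79 ± 0.20 between both responses (adjusted p = 0.020, edgeR). The share of genes raised was 43.7%, against 27.3% with upper-quartile factors (1646 raised, 4376 lowered) and 25.4% with library totals (1536 raised, 4511 lowered), which shifted the median gene by -0.10 and -0.12. Genes raised numbered 1565 without WIN replicate 2 and 1461 without WIN plus IL1B replicate 2, and genes lowered 2027 without the latter. Genes responding less numbered 530 without WIN replicate 2 and 494 without WIN plus IL1B replicate 2, against 804 with all libraries. Genes responding more numbered 550 without IL1B replicate 2, 564 without WIN replicate 2, 546 without WIN plus IL1B replicate 1 and 497 without WIN plus IL1B replicate 2.

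**Figure D4:**
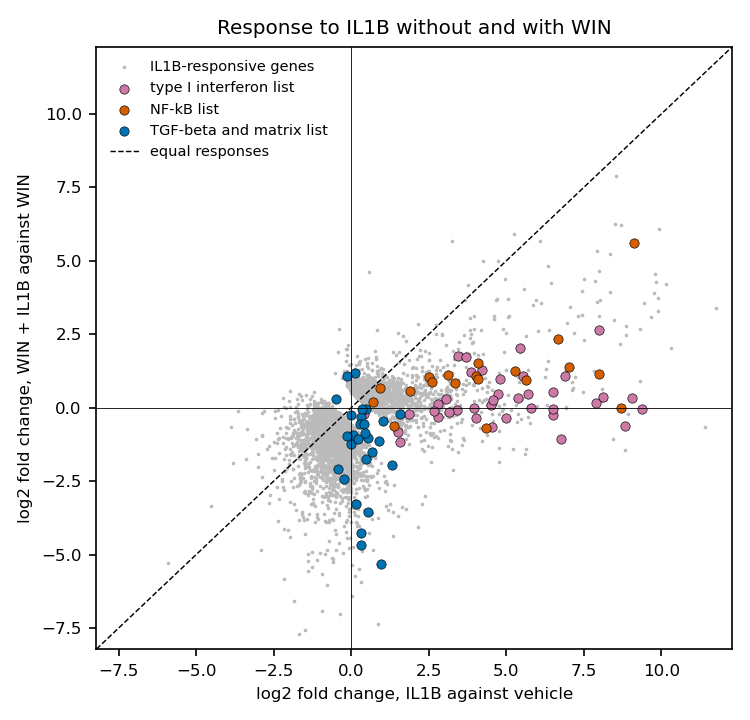
Response to IL1B without WIN (horizontal axis, log2 fold change of IL1B against vehicle) and with WIN (vertical axis, log2 fold change of WIN plus IL1B against WIN) for genes called in the average response (grey), with the tested members of 3 fixed lists in colour. The interferon list lies near 0 on the vertical axis, with a median of 0.11 against 4.66 on the horizontal one, and the NF-kB list has medians of 0.98 and 4.08.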

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

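The tests of shared libraries, scaling, uniform loss, depth, fibroblast and mural markers and RNA quality were chosen after the results were seen.

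Some genes responded to IL1B in opposite directions with and without WIN, by the interaction test and by calls in each response. They comprised 277 genes raised by IL1B alone and lowered by IL1B in WIN-treated cells, and 24 genes lowered by IL1B alone and raised with WIN. Both numbers come from the main fit and were not counted again under the alternatives. The calls that the 24 rest on varied widely with a library left out, as given below. Among the genes of the first set the interactions (log2) were -9.05 for TGM2, -7.02 for LIF, -6.89 for KRT75, -6.61 for IL11, -6.59 for PI15, -6.30 for CTGF, -5.72 for RGS4 and -5.55 for GBP1. In the second set they were 2.03 for CEBPA, 1.92 for SPEF1 and 1.84 for CISH. KRT75, PI15, RGS4, CEBPA, SPEF1 and CISH were singled out after their values were seen. RGS4, a regulator of G protein signalling, went from 11.3 ± 1.88 to 28.6 ± 2.94 CPM with IL1B alone and from 12.4 ± 1.04 to 0.501 ± 0.324 CPM with WIN. CEBPA, a transcription factor of differentiation, went from 0.897 ± 0.225 to 0.362 ± 0.0779 CPM without WIN and from 5.25 ± 0.663 to 8.83 ± 0.720 CPM with it.

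The first pattern weighed was that genes raised by IL1B were lower with WIN in stimulated cells, which both comparisons could show through the IL1B libraries they share. Sharing alone is argued against by a median log2 fold change with WIN of -1.61, the weaker of 2 ways to take each comparison from another IL1B library, where the lowest of 1000 random gene sets was at -0.19. Scaling is argued against by a lowest count of 1095 genes under 4 scalings, a test that took the place of a first one, on the interaction medians of the lists below, that had not decided it. A uniform loss of the log2 response is argued against by the spread of the loss over all genes of the pattern, with a chi-square per degree of freedom of 20.8 for the same amount lost and 21.8 for the same fraction, in a test that also took the place of that first one. Loss of the same fraction of the added transcripts on the linear scale was not fitted, so that form stays open. Whether interferon-stimulated genes lost more than NF-kB genes stays open. Their interaction medians of -4.35 and -2.95 differed by -1.40 without passing (permutation of genes between the lists, p = 0.0809). The responses left with WIN, 0.11 and 0.98, differed by -0.87 (permutation of genes between the lists, p = 0.0131). These permutations treat genes measured in the same libraries as independent, so their p-values do not measure spread between samples. An action of WIN on the signalling that IL1B starts stays an untested hypothesis.

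The second pattern weighed was the rise of endoplasmic reticulum and integrated stress genes with WIN. A shift caused by scaling is argued against by the lowest count of 39 of the 41 members higher under 4 scalings. A difference in depth is argued against by the 39 of 41 that were higher with all libraries thinned to 18847311 counts. Neither test was strict. Every group held a shallow and a deep library, and the scalings shifted the median gene by -0.15 at the most, against list medians of 2.24 and 1.95. A candidate explanation is a stress response of these cells to WIN at this concentration, a hypothesis that a single dose and time in the design could not test further.

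The third pattern weighed was the fall of ACTA2, TAGLN and genes of the TGF-beta and matrix list, such as CTGF, when IL1B was added to WIN-treated cells, with ACTA2 and TAGLN singled out after their values were seen. ACTA2 changed by -5.74 ± 0.18 and TAGLN by -4.25 ± 0.23, and the 13 other tested fibroblast and mural markers by -1.63 ± 0.23 at the lowest, for NOTCH3. If all of them came from the same cells, this argues against loss of those cells as the whole fall of ACTA2 and TAGLN. Loss of cells rich in ACTA2 and TAGLN alone could leave those 13 markers in place, so the test cannot decide on it. A partial loss and a change within cells cannot be told apart, since those markers had a median of -1.01, with COL1A1, COL1A2 and THY1 at -1.25 ± 0.26, -0.97 ± 0.18 and -1.45 ± 0.15 and COL3A1 at 1.19 ± 0.20 (named after their values were seen), all 13 were present in the vehicle cultures, and which cells expressed them was not tested. More astrocyte, neural progenitor, oligodendrocyte lineage and endothelial markers also fell than rose, with medians of -0.28, -0.47, -0.81 and -1.12. The endothelial list did not pass limma's camera, and the calls of the others were lost with an estimated correlation and without some libraries. RNA quality stays open too, since the mitochondrial share in WIN plus IL1B libraries, with a mean of 1.25%, lay inside the 1.02% to 1.66% of the other 6, but at 1.35% and 1.16% below the 1.66% and 1.36% of the WIN libraries. Histone transcripts, a further measure of RNA selection that also follows the cell cycle, summed to 59.6 ± 0.580 CPM with WIN and 25.5 ± 0.529 CPM with both.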

How the results depend on the processing

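Library totals without factors and thinning to equal depth were chosen after the data were seen. Of 20 counts of genes, none moved by more than 1.5 times with DESeq2, limma-voom, RLE factors, the stricter filter or thinned libraries. Single genes were followed under the alternatives only if named by the rule. This was done for IL1B against vehicle, WIN against vehicle, WIN plus IL1B against IL1B and the interaction. None of these genes, and no list in the 6 contrasts, went from a call in one direction to a call in the other. Whether a result that lost its call also turned was not tested, nor were the other called genes. The balance of some counts turned. More genes were raised than lowered by IL1B (1821 and 1365), and fewer with upper-quartile factors or library totals, by the counts below and 1499 and 1390 raised. Larger responses outnumbered smaller ones (910 and 804), but not at an adjusted p under 0.01, with a 2-fold minimum, or without vehicle replicate 1 (971 and 1015), IL1B replicate 2 (550 and 616) or WIN plus IL1B replicate 1 (546 and 555). WIN raised 4346 and lowered 4413, which turned with limma-voom (4383 and 4358), no filter (4835 and 4440), a 2-fold minimum, an adjusted p under 0.01 (3328 and 3255), or without vehicle replicate 2 (4441 and 4334) or WIN replicate 2 (3506 and 3237), while it leaned further down with upper-quartile factors (3713 and 5286) or library totals (3587 and 5445). More genes were lower than higher with WIN in stimulated cells (5730 and 4911) and in the average response (3212 and 2494), except with no filter (5550 and 5660) or only the groups compared (5712 and 5823) in the first and with DESeq2 (2625 and 2851) in the second. Of genes lowered by IL1B, fewer were raised than lowered by WIN (439 and 524), except with no filter (622 and 576). Where a count moved, the cause was not tested, except that a stricter threshold or fold minimum passes fewer genes by construction. Counts of genes higher and lower in both WIN effects (WIN against vehicle, WIN plus IL1B against IL1B) moved only with the fold minimum among the alternatives run. With an estimated correlation, 102 of the lists' calls over the 6 contrasts ended. Fry tests a list for a shift up or down against no change and so asks another question than camera. By fry, 45 lists passed that had not passed camera, and 2 that had did not. Groups of 2 limit every result, and the leave-out ranges show it.

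At an adjusted p under 0.01, IL1B lowered 574 genes, and IL1B in WIN-treated cells raised 552 and lowered 1658. The average response had 1408 genes raised and 1907 lowered, with 498 smaller and 460 larger responses, and the interaction 123 positive and 1302 negative. Overlaps were 85 genes raised by IL1B and by WIN, 144 lowered then raised, 219 lowered by both, and 104 opposite WIN effects.

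With a 2-fold minimum, IL1B raised 1033 and lowered 491, WIN raised 2253 and lowered 2150, WIN in stimulated cells raised 2766, and IL1B in WIN-treated cells raised 273 and lowered 1626. The average response had 563 raised and 926 lowered, with 412 smaller and 339 larger, and 239 interactions were positive. Overlaps were 789 raised then lowered, 30 raised by both, 124 lowered then raised, 149 lowered by both, 3610 shared and 60 opposite WIN effects.

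With library totals, IL1B lowered 3084, the average response raised 1536, 980 interactions were positive, and overlaps were 118 raised by both, 1049 lowered then raised and 1095 lowered by both. With upper-quartile factors, IL1B lowered 2471, the average response raised 1646, and these overlaps were 140, 804 and 943. Without a low-count filter, IL1B in WIN-treated cells raised 2595 and 954 interactions were positive. With only the groups compared, IL1B lowered 735 genes and raised 2726 in WIN-treated cells. With a replicate block, IL1B lowered 2477 genes and raised 2949 in WIN-treated cells, 1343 interactions were positive and 1605 responses larger, and overlaps were 576 raised by both, 901 lowered then raised, 958 lowered by both and 307 opposite WIN effects.

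With 1 library left out, IL1B lowered 513 to 1750 genes, and IL1B in WIN-treated cells raised 354 to 2764 and lowered 1333 to 3502. Interactions ranged from 148 to 1231 positive and 1360 to 2737 negative. The average response ranged from 1461 to 3666 raised and 2027 to 3688 lowered, with 494 to 1015 smaller and 497 to 1179 larger. Overlaps ranged from 92 to 601 raised by both, 133 to 582 lowered then raised, 206 to 723 lowered by both, and 126 to 309 opposite WIN effects. Genes raised by IL1B stayed at 1332 to 2722, and genes raised by IL1B and lowered by WIN at 1021 to 1615.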

Other observations

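No test of an explanation was run for these observations, which were all described after the data were seen. In fatty acid synthesis 10 of 18 tested genes rose with WIN against vehicle and 2 fell, with the same counts when adjusted over the list alone (limma's camera adjusted p = 0.057, which did not pass, and adjusted p = 0.32 with an estimated correlation). The desaturase gene FADS1 was at 145 ± 8.50 CPM with vehicle, 573 ± 108 CPM with WIN and 576 ± 43.2 CPM with WIN plus IL1B. The list passed without WIN replicate 2 (limma's camera adjusted p = 0.038) and with fry in limma (adjusted p = 0.00064). In WIN plus IL1B against IL1B the same list had 10 genes higher and 6 lower (limma's camera adjusted p = 0.11, and fry adjusted p = 0.00033). Of 32 hypoxia and glycolysis genes, 12 rose and 4 fell with WIN, the same when adjusted over the list alone (limma's camera adjusted p = 0.095). That list passed without vehicle replicate 2, with 16 higher and 3 lower (limma's camera adjusted p = 0.026), and with fry in limma (adjusted p = 0.0083). Without vehicle replicate 1 its genes were 11 higher and 9 lower. HK2, the first enzyme of glycolysis, went from 13.7 ± 1.02 to 101 ± 10.0 CPM. FADS1 and HK2 were chosen after their values were seen.

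Of 18 neuron markers 9 fell and 4 rose with WIN against vehicle, or 11 and 4 when adjusted over the list alone (limma's camera adjusted p = 0.072), and the list passed with the stricter low-count filter (limma's camera adjusted p = 0.039) and with fry in limma (adjusted p = 0.00037). Their summed level was 1603 ± 128 CPM with vehicle, 1573 ± 1.56 CPM with IL1B, 764 ± 4.93 CPM with WIN and 675 ± 11.4 CPM with both. Microglia and macrophage markers, with 3 genes tested and so no list test, summed to 1.85 ± 0.527 CPM with vehicle, 1.26 ± 0.398 CPM with IL1B, 1.21 ± 0.0364 CPM with WIN and 0.327 ± 0.232 CPM with both. Of 22 p53 target genes 6 rose and 9 fell with WIN, the same when adjusted over the list alone (limma's camera adjusted p = 0.76). Of 19 heat shock genes 9 rose and 2 fell, also when adjusted over the list alone (limma's camera adjusted p = 0.20, and fry adjusted p = 0.0055).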
